A study of Homo sapiens and Mus musculus with 24 samples.

How the data were processed

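Total RNA of 12 LNCaP and 12 mouse CAF libraries was sequenced, per the labels' protocols after Trizol extraction and with the NEBNext Ultra kit on a HiSeq instrument. LNCaP cells were grown in RPMI 1640 and CAFs in DMEM, each with 10% FBS, and the labels state 2 biological replicates per condition. The deposited LNCaP table gives RPKM per the file headers. The deposited CAF table gives TPM per the file headers. The submitters' processing notes name HISAT2, HTSeq and DESeq2, and the genome builds hg19 and mm10, without the role, order or version of each, so how reads of the human cells and of any fibroblasts in the cocultures were separated is not given in the sources used here. The files identify genes by symbol only and give no positions.

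The LNCaP table holds 44591 names, of which 27 were calendar dates and were removed, which left 44564, and 2 names occur repeatedly. The CAF table holds 39089 names. Column totals of the RPKM table ran from 414991 to 450923 and are not a depth. The smallest common step of each gene across libraries was solved where at least 6 libraries were above 0. Steps were solved to within 0.02 reads, and a value within 0.05 reads of a whole number was called whole, as all solved LNCaP values were. This gave the number of reads behind at least 99.9% of each LNCaP total and 99.8% of each CAF total. The Sox4-labelled columns and 54 genes of the DMSO columns are exceptions that the report describes. Steps of 0.3 read were looked for on simulated columns too, where 54 of 54 genes multiplied by 0.3 were found, and 11 other genes of 2717 solved were wrongly found off whole reads.

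The groups, the 18 comparisons, the tests, the gene lists, the rule for named genes and the alternatives not marked below as added were set before the data were examined. The comparison of both agents with the ADT mice, the set of 54 genes, the division by 0.3, the fits without whole groups and all tests of explanations were added after the data were examined. Each table was fitted once with limma 3.58.1 in R 4.3.3, on log2(value + 1), with a mean-variance trend, 6 groups and no block, over genes at 1 or more in at least 2 libraries. This left 16042 LNCaP and 14988 CAF genes and 6 residual degrees of freedom, shared by all groups. P values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and all tests are two-sided. The 2 libraries of 1 number in different groups were checked for pairing: the correlation of their deviations across genes, which are not independent, lay between -0.0617 and 0.0931 for all pairs of groups but the Sox4-labelled and ADT columns, at 0.946. Named genes had an adjusted p under the threshold, a mean of at least 1 in a group compared, libraries of both groups apart (differences of effects: adjusted p only) and an official symbol that is not a clone or locus name. They are the 10 largest rises and 10 largest falls, up to 4 members of each list with the smallest p, and genes set at the start, among them KLK3, FKBP5, Sox4, Spp1, Acta2, Fkbp5 and Trp53. Some genes that the rule names are not reported here. 1 Y-linked gene that the rule names was left out of the text.

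Lists were tested with camera from limma with a preset correlation of 0.01 between genes, adjusted over the lists of that organism, and again with an estimated correlation. Where a list passed with the first only, the adjusted p with the second is printed beside it, and a list call without a second p passed both ways. The 16 human lists are androgen-activated targets, androgen-repressed genes, cell cycle, ERK pathway output, TGF-beta response, interferon response, NF-kB and chemokines, hypoxia and glycolysis, cholesterol and lipid synthesis, integrated stress and unfolded protein response, p53 targets, steroid synthesis and metabolism, and neuroendocrine, luminal epithelial, basal and mesenchymal, and fibroblast markers. The 19 mouse lists are myofibroblastic CAF, inflammatory CAF, antigen presentation, collagens and matrix, matrix proteases and inhibitors, TGF-beta response, androgen and steroid responsive genes, Sox4 and SWI/SNF subunits, cell cycle, interferon response, NF-kB and chemokines, hypoxia and glycolysis, cholesterol and lipid synthesis, integrated stress and unfolded protein response, p53 targets, and epithelial, macrophage and leukocyte, endothelial, and pericyte, muscle, fat and glial markers. No gene of the marker lists is in another list.

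The alternatives were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling, the replicate number as a block, and each library of a comparison left out in turn. Leaving out 1 of 2 libraries assumes that the lone library varies like the other groups. For the CAFs, the division by 0.3 and fits without the Sox4-labelled columns or without the libraries with both agents were added. The test was run on simulated data with the depth of these libraries, but 1 spread for all genes and fewer changed genes. At 1.5-, 2- and 4-fold changes it found 14.9%, 73.1% and 95.5% of changed genes for LNCaP alone with 7 unchanged genes among 129 calls, and 40.3%, 77.6% and 93.9% for CAFs with 3 among 146. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. With 2 libraries per group no test for an outlying library was run.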

Results

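RNA was measured in 24 libraries that form 12 groups of 2. 6 groups hold LNCaP cells, an androgen-responsive human prostate cancer epithelial line, and 6 hold mouse cancer-associated fibroblasts (CAFs). The LNCaP cells were grown alone or with fibroblasts that the labels call CCAFs or CRPCCAFs, without spelling these names out, and received the vehicle DMSO or 1 µM enzalutamide, an antiandrogen, to day 7. The CAFs were isolated from mice whose genotype in the labels includes Trp53PC-/-. They received DMSO, 1 µM enzalutamide, 5 ng/ml TGF-beta1 or both agents to day 7. The other 2 CAF groups, labelled as Sox4-overexpressing and as taken from ADT mice, were collected at day 0 without treatment. The labels do not spell out ADT. Reads per library, recovered from the smallest steps of the values, ran from 17850431 to 22187880 for LNCaP and from 17372418 to 21040105 for the CAFs other than the Sox4-labelled columns, where no read number could be recovered. Every ± below is the SD of the 2 libraries of a group, every adjusted p of a gene is from limma, and every list is one fixed before the data were examined unless stated otherwise. Log2 changes are on log2(value + 1), so they understate the fold of genes with low values, and list medians are medians of log2 changes.

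The first question was what enzalutamide did to LNCaP cells without fibroblasts. KLK3, the gene of prostate-specific antigen, averaged 58.5 ± 4.18 RPKM against 1194 ± 69.4 (20.4-fold lower, log2 -4.33, SE 0.0537, adjusted p = 2.0e-10). The kallikrein KLK2 (40.3-fold, log2 -4.52, SE 0.0702) fell too, as did RRM2 (11.4-fold, log2 -3.30, SE 0.0640), a subunit of the enzyme that makes deoxyribonucleotides, and KCNN2 (9.37-fold, log2 -2.87, SE 0.0779), a calcium-activated potassium channel. IGFBP3, a secreted binder of insulin-like growth factors, averaged 157 ± 3.26 RPKM against 7.45 ± 0.591 (21.1-fold higher, log2 4.23, SE 0.0620, adjusted p = 3.5e-10). UGT2B17 (8.28-fold, log2 2.94, SE 0.0698), which inactivates androgens, CAMK2N1 (6.55-fold, log2 2.66, SE 0.0591), an inhibitor of calcium/calmodulin kinase II, and DDC (6.14-fold, log2 2.55, SE 0.0390), a decarboxylase of aromatic amino acids, rose as well. FKBP5, an androgen-induced co-chaperone, averaged 2.81 ± 0.0487 RPKM against 15.4 ± 0.440 (5.48-fold lower, log2 -2.11, SE 0.0546, adjusted p = 3.2e-09).

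Among the androgen-activated targets, 2 rose and 30 fell of 34 (2 and 30 adjusted over the list alone), with SLC45A3 at -1.85. Their median was -1.02 (camera adjusted p = 2.6e-15). Within the androgen-repressed genes, 11 rose and 1 fell of 13 (11 and 1 adjusted over the list alone), with ACKR3 at 1.69. Their median was 1.35 (camera adjusted p = 1.9e-06). For cell cycle genes, 0 rose and 32 fell of 32 (0 and 32 adjusted over the list alone), with CDK1 at -2.57 and MCM4 at -2.16. Their median was -2.14 (camera adjusted p = 1.6e-25). Across hypoxia and glycolysis genes, 1 rose and 14 fell of 18 (1 and 14 adjusted over the list alone), with LDHA at -1.68. Their median was -0.68 (camera adjusted p = 2.0e-06, adjusted p = 0.15 with an estimated correlation). Of cholesterol and lipid synthesis genes, 2 rose and 14 fell of 20 (2 and 14 adjusted over the list alone). Their median was -0.26 (camera adjusted p = 0.0012). Among TGF-beta response genes, 8 rose and 2 fell of 15 (8 and 2 adjusted over the list alone), with ID1 at 2.44. Their median was 0.63 (camera adjusted p = 0.0099, adjusted p = 0.072 with an estimated correlation). Within integrated stress and unfolded protein genes, 0 rose and 13 fell of 20 (0 and 13 adjusted over the list alone). Their median was -0.25 (camera adjusted p = 0.00075, adjusted p = 0.15 with an estimated correlation). For p53 targets, 3 rose and 10 fell of 18 (4 and 10 adjusted over the list alone). Their median was -0.30 (camera adjusted p = 0.025, adjusted p = 0.10 with an estimated correlation). Across ERK pathway output genes, 2 rose and 3 fell of 14 (2 and 3 adjusted over the list alone), with MYC at -2.31 and SPRY4 at 2.58. Their median was 0.0094, their mean -0.073 and the test direction down (camera adjusted p = 0.67). Of interferon response genes, 7 rose and 3 fell of 22 (7 and 3 adjusted over the list alone). Their median was -0.0088, their mean 0.010 and the test direction up (camera adjusted p = 0.88). Among NF-kB and chemokine genes, 1 rose and 2 fell of 11 (1 and 1 adjusted over the list alone). Their median was -0.0095 (camera adjusted p = 0.67). Within steroid synthesis and metabolism genes, 3 rose and 5 fell of 11 (3 and 5 adjusted over the list alone). Their median was -0.14 (camera adjusted p = 0.41). For luminal epithelial markers, 9 rose and 1 fell of 16 (9 and 1 adjusted over the list alone). Their median was 0.24 (camera adjusted p = 0.023, adjusted p = 0.15 with an estimated correlation). Across basal and mesenchymal markers, 1 rose and 5 fell of 8 (1 and 5 adjusted over the list alone). Their median was -0.62 (camera adjusted p = 0.087). Of neuroendocrine markers, 1 rose and 1 fell of 3 (2 and 1 adjusted over the list alone). Their median was 0.47 (camera adjusted p = 0.58). Among fibroblast markers, 6 rose and 1 fell of 10 (6 and 2 adjusted over the list alone), with COL6A1 at 1.03. Their median was 0.50 (camera adjusted p = 0.051). Of the markers that were measured, LNCaP alone under DMSO held 15 of 16 luminal, 4 of 8 basal and mesenchymal, 2 of 3 neuroendocrine and 7 of 10 fibroblast markers at 1 RPKM or more. The fibroblast list names 25 genes in all. limma's test passed for 8887 of 16042 genes, 4831 higher and 4056 lower as deposited and 4194 higher and 4564 lower after median-of-ratios scaling.

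**Figure D1:**
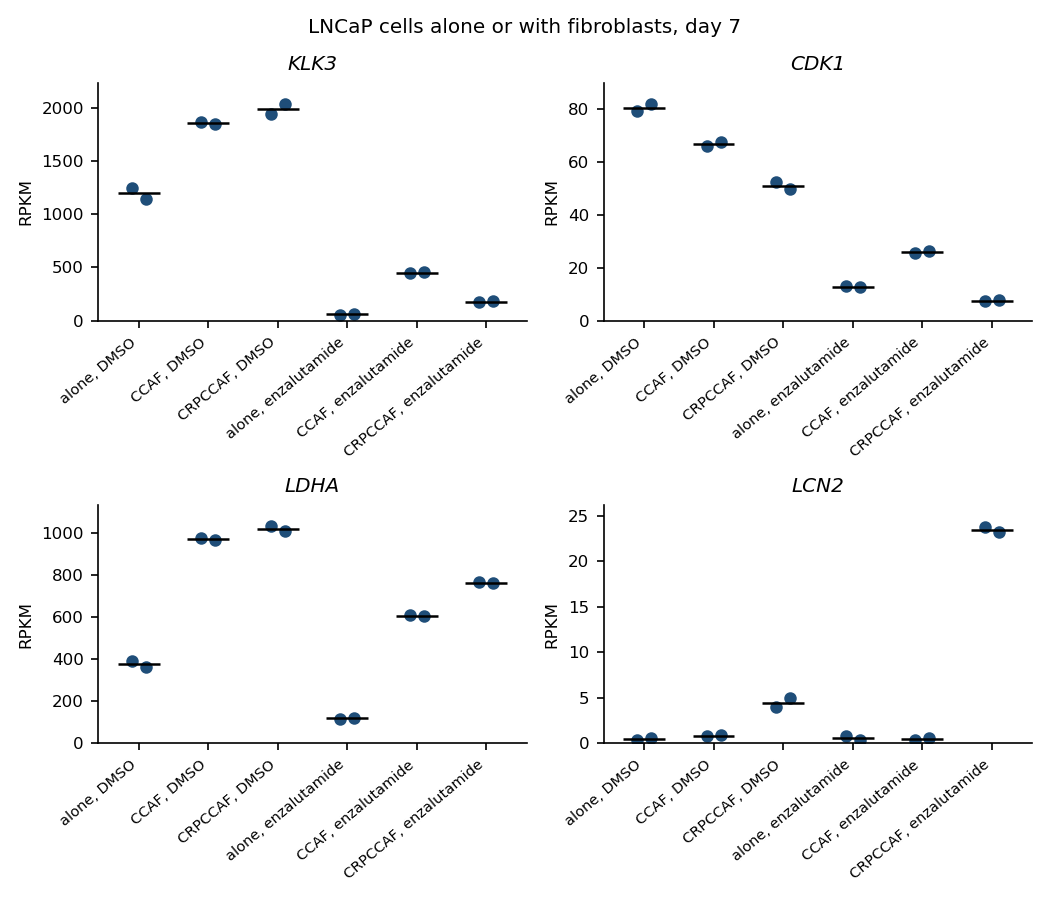
RPKM of KLK3, CDK1, LDHA and LCN2 in each library of the 6 LNCaP groups, on the y axis of each panel, with points for the 2 libraries of a group and a black bar for their mean. KLK3 is lower under enzalutamide in all 3 kinds of culture, and LCN2 is highest with CRPCCAFs under enzalutamide.

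With CCAFs present, enzalutamide lowered KLK3 to 449 ± 6.84 RPKM against 1855 ± 8.85 (4.13-fold lower, log2 -2.04, SE 0.0537, adjusted p = 7.0e-09). ADAM7 (19.9-fold, log2 -3.70, SE 0.0736), KLK2 (10.5-fold, log2 -3.29, SE 0.0702) and TRPM8 (12.8-fold, log2 -2.73, SE 0.0794), an androgen-regulated cation channel, fell further in fold. AOC1, a diamine oxidase, averaged 15.6 ± 0.373 RPKM against 0.209 ± 0.0908 (74.6-fold higher, log2 3.78, SE 0.0857, adjusted p = 3.5e-09). UGT2B17 (12.1-fold, log2 3.42, SE 0.0698), DDC (9.92-fold, log2 3.19, SE 0.0390) and CP (15.9-fold, log2 2.75, SE 0.0721), the copper-carrying ferroxidase ceruloplasmin, rose. FKBP5 averaged 4.13 ± 0.143 RPKM against 23.2 ± 0.322 (5.62-fold lower, log2 -2.24, SE 0.0546, adjusted p = 5.1e-09). Within the androgen-activated targets, 2 rose and 31 fell of 34 (2 and 31 adjusted over the list alone), with TMPRSS2 at -2.32. Their median was -1.34 (camera adjusted p = 1.5e-21). For cell cycle genes, 0 rose and 32 fell of 32 (0 and 32 adjusted over the list alone), with CDK1 at -1.33. Their median was -1.06 (camera adjusted p = 9.5e-23). Across fibroblast markers, 6 rose and 2 fell of 10 (6 and 2 adjusted over the list alone). Their median was 0.39 (camera adjusted p = 0.12). limma's test passed for 7756 of 16042 genes, 4306 higher and 3450 lower as deposited and 3626 higher and 4109 lower after median-of-ratios scaling.

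With CRPCCAFs present, KLK3 under enzalutamide averaged 179 ± 1.29 RPKM against 1988 ± 60.9 (11.1-fold lower, log2 -3.47, SE 0.0537, adjusted p = 1.7e-10). KLK2 (29.8-fold, log2 -4.61, SE 0.0702), RRM2 (14.3-fold, log2 -3.54, SE 0.0640), the proto-oncogene MYC (9.11-fold, log2 -3.06, SE 0.0405) and MYBL2 (9.79-fold, log2 -2.95, SE 0.0571), a transcription factor of the cell cycle, fell. CP averaged 71.5 ± 0.00758 RPKM against 4.11 ± 0.393 (17.4-fold higher, log2 3.83, SE 0.0721, adjusted p = 4.9e-10). AOC1 (49.9-fold, log2 4.14, SE 0.0857), UGT2B17 (21.3-fold, log2 4.02, SE 0.0698) and IGFBP5 (8.52-fold, log2 2.69, SE 0.112), another binder of insulin-like growth factors, rose. FKBP5 averaged 2.60 ± 0.0839 RPKM against 23.2 ± 1.41 (8.95-fold lower, log2 -2.75, SE 0.0546, adjusted p = 6.4e-10). Of NF-kB and chemokine genes, 10 rose and 1 fell of 11 (10 and 1 adjusted over the list alone), with IL1B at 2.18, LCN2 at 2.18 and CXCL8 at 1.14. Their median was 0.93 (camera adjusted p = 0.00050). Among cell cycle genes, 0 rose and 32 fell of 32 (0 and 32 adjusted over the list alone). Their median was -2.16 (camera adjusted p = 1.1e-26). Within the androgen-activated targets, 2 rose and 31 fell of 34 (2 and 31 adjusted over the list alone). Their median was -1.40 (camera adjusted p = 2.4e-18). For fibroblast markers, 6 rose and 1 fell of 10 (7 and 1 adjusted over the list alone). Their median was 0.52 (camera adjusted p = 0.022, adjusted p = 0.14 with an estimated correlation). limma's test passed for 8848 of 16042 genes, 4885 higher and 3963 lower as deposited and 4167 higher and 4496 lower after median-of-ratios scaling.

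The next comparisons asked what coculture did without the drug. With CCAFs under DMSO, PLOD2, a collagen lysyl hydroxylase, averaged 19.6 ± 0.0774 RPKM against 2.13 ± 0.438 (9.18-fold higher, log2 2.72, SE 0.0901, adjusted p = 2.4e-07). NDRG1, a gene induced by low oxygen and by androgen, averaged 135 ± 1.22 RPKM against 29.7 ± 1.52 (4.53-fold higher, log2 2.14, SE 0.0394, adjusted p = 7.8e-09). NDUFA4L2 (6.32-fold, log2 2.64, SE 0.168), a mitochondrial protein induced by hypoxia-inducible factor, SLC16A3 (4.56-fold, log2 2.04, SE 0.132), the lactate exporter MCT4, AKAP12 (7.97-fold, log2 2.24, SE 0.0765), a scaffold for protein kinase A, and HMOX1 (3.83-fold, log2 1.77, SE 0.0843), heme oxygenase, rose too. KLK3 averaged 1855 ± 8.85 RPKM against 1194 ± 69.4 (1.55-fold higher, log2 0.64, SE 0.0537, adjusted p = 6.9e-05) and FKBP5 23.2 ± 0.322 RPKM against 15.4 ± 0.440 (1.51-fold higher, log2 0.56, SE 0.0546, adjusted p = 0.00019). Across hypoxia and glycolysis genes, 16 rose and 0 fell of 18 (17 and 0 adjusted over the list alone), with PFKFB3 at 1.61 and PGK1 at 1.44. Their median was 0.98 (camera adjusted p = 1.5e-30). Of the androgen-activated targets, 21 rose and 0 fell of 34 (25 and 0 adjusted over the list alone), with TRPM8 at 1.39. Their median was 0.49 (camera adjusted p = 3.5e-24). Among cell cycle genes, 0 rose and 11 fell of 32 (0 and 15 adjusted over the list alone). Their median was -0.21 (camera adjusted p = 1.4e-06). Within fibroblast markers, 2 rose and 0 fell of 10 (2 and 1 adjusted over the list alone), with FN1 at 0.89. Their median was 0.038 (camera adjusted p = 0.30). The 10 largest falls were mostly short RNA genes. limma's test passed for 1518 of 16042 genes, 878 higher and 640 lower. The count was 701 without LNCaP alone DMSO library 1, 824 without library 2, 640 without CCAF DMSO library 1 and 699 without library 2, and 9 of 22 named genes, all of them among the falls or microRNA genes, lost their call in at least 1 of these fits.

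With CRPCCAFs under DMSO, C8orf4, a positive regulator of Wnt signalling, averaged 27.6 ± 0.338 RPKM against 0.179 ± 0.0792 (154-fold higher, log2 4.60, SE 0.0848, adjusted p = 1.6e-09). MMP7, the protease matrilysin, averaged 41.8 ± 0.281 RPKM against 1.03 ± 0.0363 (40.5-fold higher, log2 4.40, SE 0.0933, adjusted p = 4.3e-09), and CYP26A1, which degrades retinoic acid, 11.3 ± 0.925 RPKM against 0.0510 ± 0.0205 (221-fold higher, log2 3.54, SE 0.0879, adjusted p = 9.4e-09). HMOX1 (13.7-fold, log2 3.57, SE 0.0843), NDUFA4L2 (13.5-fold, log2 3.72, SE 0.168), DHRS3 (9.99-fold, log2 3.09, SE 0.0835), a retinal reductase, and ATP1B1 (7.86-fold, log2 2.96, SE 0.0335), a subunit of the sodium pump, rose, and UGT2B17 (3.501-fold, log2 -1.52, SE 0.0698) and MMP16 (2.74-fold, log2 -1.26, SE 0.110), a membrane metalloprotease, fell. KLK3 averaged 1988 ± 60.9 RPKM against 1194 ± 69.4 (1.66-fold higher, log2 0.74, SE 0.0537, adjusted p = 1.0e-05) and FKBP5 23.2 ± 1.41 RPKM against 15.4 ± 0.440 (1.51-fold higher, log2 0.57, SE 0.0546, adjusted p = 6.5e-05). For hypoxia and glycolysis genes, 18 rose and 0 fell of 18 (18 and 0 adjusted over the list alone), with PFKFB3 at 1.95 and PGK1 at 1.86. Their median was 1.41 (camera adjusted p = 3.3e-22). Across NF-kB and chemokine genes, 8 rose and 0 fell of 11 (8 and 0 adjusted over the list alone), with LCN2 at 1.92 and CXCL8 at 1.297. Their median was 0.69 (camera adjusted p = 2.9e-06). Of ERK pathway output genes, 10 rose and 1 fell of 14 (10 and 1 adjusted over the list alone), with FOS at 2.87 and EGR1 at 2.87. Their median was 0.37 (camera adjusted p = 2.8e-05). Among cell cycle genes, 0 rose and 32 fell of 32 (0 and 32 adjusted over the list alone). Their median was -0.51 (camera adjusted p = 4.4e-16). Within fibroblast markers, 5 rose and 0 fell of 10 (5 and 0 adjusted over the list alone), with FN1 at 1.76 and COL1A1 at 0.63. Their median was 0.27 (camera adjusted p = 0.00085). limma's test passed for 4905 of 16042 genes, 2286 higher and 2619 lower. Of the 22 named genes, 6, all short RNA genes or IGKC, lost their call without 1 library.

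Set against each other under DMSO, CRPCCAF cocultures held more CYP26A1 than CCAF cocultures, 11.3 ± 0.925 RPKM against 0.1998 ± 0.0466 (56.4-fold higher, log2 3.35, SE 0.0879, adjusted p = 5.4e-08), and more MMP7, 41.8 ± 0.281 RPKM against 3.94 ± 0.237 (10.6-fold higher, log2 3.12, SE 0.0933, adjusted p = 1.2e-07). C8orf4 (46.4-fold, log2 4.17, SE 0.0848), FOS (14.2-fold, log2 2.69, SE 0.0988), IGFBP3 (7.23-fold, log2 2.65, SE 0.0620) and CYR61 (4.73-fold, log2 2.04, SE 0.0680), a matricellular protein, were higher as well. KLK3 at 1988 ± 60.9 RPKM against 1855 ± 8.85 (1.07-fold higher, log2 0.099, SE 0.0537, adjusted p = 0.26) and FKBP5 (adjusted p = 1.0) did not pass. For NF-kB and chemokine genes, 8 rose and 0 fell of 11 (10 and 0 adjusted over the list alone). Their median was 0.62 (camera adjusted p = 4.1e-09). Across cell cycle genes, 0 rose and 21 fell of 32 (0 and 30 adjusted over the list alone), with MKI67 at -0.53. Their median was -0.30 (camera adjusted p = 3.5e-16). Of TGF-beta response genes, 7 rose and 0 fell of 15 (7 and 1 adjusted over the list alone). Their median was 0.22 (camera adjusted p = 1.0e-06). Among fibroblast markers, 5 rose and 0 fell of 10 (5 and 0 adjusted over the list alone), with FN1 at 0.87. Their median was 0.25 (camera adjusted p = 0.00025). limma's test passed for 2156 of 16042 genes, 1127 higher and 1029 lower as deposited and 1108 higher and 1147 lower after median-of-ratios scaling. The count was 934 without CCAF DMSO library 1, 821 without CCAF DMSO library 2 and 1319 without CRPCCAF DMSO library 2, and 8 of 20 named genes, all short RNA genes or IGKC among the falls, lost their call without 1 library.

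Under enzalutamide, KLK3 was higher with CCAFs than alone, 449 ± 6.84 RPKM against 58.5 ± 4.18 (7.67-fold higher, log2 2.92, SE 0.0537, adjusted p = 3.9e-09), as was KLK2 (9.01-fold, log2 2.46, SE 0.0702). LDHA, lactate dehydrogenase A, averaged 606 ± 3.63 RPKM against 117 ± 2.97 (5.18-fold higher, log2 2.36, SE 0.0397, adjusted p = 3.4e-09). NDUFA4L2 (13.3-fold, log2 3.53, SE 0.168), PLOD2 (34.6-fold, log2 2.60, SE 0.0901) and CP (9.96-fold, log2 2.45, SE 0.0721) were higher and IGFBP3 (4.13-fold, log2 -2.02, SE 0.0620) was lower. FKBP5 averaged 4.13 ± 0.143 RPKM against 2.81 ± 0.0487 (1.47-fold higher, log2 0.43, SE 0.0546, adjusted p = 0.00056). Within cell cycle genes, 32 rose and 0 fell of 32 (32 and 0 adjusted over the list alone), with RRM2 at 1.85 and CDC6 at 1.47. Their median was 0.85 (camera adjusted p = 9.8e-32). For hypoxia and glycolysis genes, 15 rose and 0 fell of 18 (17 and 0 adjusted over the list alone). Their median was 0.96 (camera adjusted p = 4.2e-20, adjusted p = 0.055 with an estimated correlation). Across the androgen-activated targets, 15 rose and 4 fell of 34 (17 and 6 adjusted over the list alone). Their median was 0.15 (camera adjusted p = 0.00059). Of fibroblast markers, 1 rose and 3 fell of 10 (2 and 3 adjusted over the list alone). Their median was -0.00040, their mean 0.0073 and the test direction down (camera adjusted p = 0.55). limma's test passed for 3107 of 16042 genes, 1903 higher and 1204 lower. The count was 1672 without LNCaP alone enzalutamide library 1, 1951 without library 2, 1874 without CCAF enzalutamide library 1 and 1739 without library 2. Of the 21 named genes, 5, all microRNA genes or IGKC, lost their call without 1 library.

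With CRPCCAFs under enzalutamide, C8orf4 averaged 63.5 ± 0.617 RPKM against 0.205 ± 0.0217 (311-fold higher, log2 5.74, SE 0.0848, adjusted p = 2.0e-10) and CP 71.5 ± 0.00758 RPKM against 0.992 ± 0.127 (72.0-fold higher, log2 5.19, SE 0.0721, adjusted p = 1.9e-10). CYP26A1 (1594-fold, log2 5.02, SE 0.0879), IGFBP5 (141-fold, log2 4.33, SE 0.112), NMB (28.7-fold, log2 4.44, SE 0.152), the peptide neuromedin B, SDCBP2 (76.9-fold, log2 4.81, SE 0.128), which encodes syntenin-2 and shares exons with the readthrough gene FKBP1A-SDCBP2, and HMOX1 (19.7-fold, log2 4.10, SE 0.0843) were higher than in LNCaP alone. KLK3 averaged 179 ± 1.29 RPKM against 58.5 ± 4.18 (3.06-fold higher, log2 1.60, SE 0.0537, adjusted p = 3.0e-08). FKBP5 at 2.60 ± 0.0839 RPKM against 2.81 ± 0.0487 (1.08-fold lower, log2 -0.081, SE 0.0546, adjusted p = 0.28) did not pass. Among NF-kB and chemokine genes, 11 rose and 0 fell of 11 (11 and 0 adjusted over the list alone), with LCN2 at 4.003 and CXCL8 at 2.51. Their median was 1.81 (camera adjusted p = 2.1e-11). Within hypoxia and glycolysis genes, 18 rose and 0 fell of 18 (18 and 0 adjusted over the list alone), with VEGFA at 2.72. Their median was 1.58 (camera adjusted p = 1.8e-21). For cell cycle genes, 0 rose and 29 fell of 32 (0 and 31 adjusted over the list alone), with PLK1 at -0.87. Their median was -0.58 (camera adjusted p = 1.8e-14). Across steroid synthesis and metabolism genes, 5 rose and 2 fell of 11 (5 and 2 adjusted over the list alone), with AKR1C1 at 2.83. Their median was 0.26 (camera adjusted p = 0.0072, adjusted p = 0.15 with an estimated correlation). Of fibroblast markers, 5 rose and 1 fell of 10 (6 and 2 adjusted over the list alone), with FN1 at 1.84. Their median was 0.46 (camera adjusted p = 0.038, adjusted p = 0.15 with an estimated correlation). limma's test passed for 5788 of 16042 genes, 2650 higher and 3138 lower, and 6 of 21 named genes, all short RNA genes or IGKC, lost their call without 1 library.

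Between the cocultures under enzalutamide, LCN2, the iron-siderophore binder lipocalin 2, averaged 23.5 ± 0.400 RPKM against 0.429 ± 0.110 (54.7-fold higher, log2 4.10, SE 0.152, adjusted p = 9.8e-08) with CRPCCAFs over CCAFs. CYP26A1 (155-fold, log2 4.77, SE 0.0879), IGFBP5 (113-fold, log2 4.28, SE 0.112) and HMOX1 (19.7-fold, log2 4.11, SE 0.0843) were higher and RRM2 (6.22-fold, log2 -2.37, SE 0.0640), MKI67 (5.49-fold, log2 -1.85, SE 0.0733), a marker of cycling cells, and AURKB (5.96-fold, log2 -1.90, SE 0.106), a mitotic kinase, were lower. KLK3 averaged 179 ± 1.29 RPKM against 449 ± 6.84 (2.51-fold lower, log2 -1.32, SE 0.0537, adjusted p = 1.5e-07) and FKBP5 2.60 ± 0.0839 RPKM against 4.13 ± 0.143 (1.59-fold lower, log2 -0.51, SE 0.0546, adjusted p = 9.0e-05). Among cell cycle genes, 0 rose and 32 fell of 32 (0 and 32 adjusted over the list alone). Their median was -1.39 (camera adjusted p = 1.4e-31). Within NF-kB and chemokine genes, 11 rose and 0 fell of 11 (11 and 0 adjusted over the list alone). Their median was 1.56 (camera adjusted p = 6.9e-12). For the androgen-activated targets, 7 rose and 18 fell of 34 (7 and 18 adjusted over the list alone). Their median was -0.23 (camera adjusted p = 0.0097, adjusted p = 0.057 with an estimated correlation). Across fibroblast markers, 6 rose and 0 fell of 10 (7 and 0 adjusted over the list alone). Their median was 0.38 (camera adjusted p = 0.00061). limma's test passed for 5197 of 16042 genes, 2226 higher and 2971 lower.

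Whether enzalutamide acted differently beside CCAFs was tested as the difference of its 2 effects, with CCAFs minus alone, in log2. For KLK3 it was 2.28 (SE 0.0759, adjusted p = 2.0e-06), so the fall was smaller with CCAFs, and for RRM2 1.76 (SE 0.0905, adjusted p = 1.8e-05). CP differed by 2.40 (SE 0.102, adjusted p = 9.6e-06). The drug's effect was lower with CCAFs for IGFBP3 at -1.66 (SE 0.0876, adjusted p = 1.8e-05), HMOX1 at -1.78 (SE 0.119, adjusted p = 3.9e-05), AKAP12 at -1.74 (SE 0.108, adjusted p = 3.0e-05) and the vessel regulator ANGPT2 at -1.37 (SE 0.128, adjusted p = 0.00022). FKBP5 at -0.13 (SE 0.0773, adjusted p = 0.37) did not pass. Of cell cycle genes, 31 differences were positive and 0 negative of 32 (32 and 0 adjusted over the list alone), with CDK1 at 1.24 and MCM4 at 1.11. Their median was 1.07 (camera adjusted p = 7.5e-45). Among the androgen-activated targets, 4 differences were positive and 12 negative of 34 (5 and 15 adjusted over the list alone). Their median was -0.20 (camera adjusted p = 6.9e-05). Within fibroblast markers, 0 differences were positive and 3 negative of 10 (1 and 3 adjusted over the list alone), with FN1 at -0.73. Their median was -0.23 (camera adjusted p = 0.033, adjusted p = 0.18 with an estimated correlation). limma's test passed for 1125 of 16042 genes, 732 higher and 393 lower. The count was 642 without LNCaP alone DMSO library 1, 623 without LNCaP alone enzalutamide library 1, 648 and 628 without CCAF DMSO libraries 1 and 2, and 718 and 647 without CCAF enzalutamide libraries 1 and 2. Of the 21 named genes, 10 lost their call without 1 library.

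The same difference was tested for CRPCCAFs minus alone. CP differed by 3.48 (SE 0.102, adjusted p = 6.0e-07), IGFBP5 by 2.60 (SE 0.158, adjusted p = 2.9e-05), LCN2 by 2.08 (SE 0.214, adjusted p = 0.00052) and NFKBIZ, a regulator of NF-kB, by 1.96 (SE 0.136, adjusted p = 6.1e-05). KLK3 differed by 0.86 (SE 0.0759, adjusted p = 0.00020), FKBP5 by -0.65 (SE 0.0773, adjusted p = 0.0011) and IGFBP3 by -1.89 (SE 0.0876, adjusted p = 5.9e-06). MMP7 differed by -1.58 (SE 0.132, adjusted p = 0.00016), with means of 6.09 ± 0.873 RPKM against 41.8 ± 0.281 for enzalutamide and DMSO with CRPCCAFs. With a pseudocount of 0.1 its difference was 0.74 and did not pass. For NF-kB and chemokine genes, 9 differences were positive and 0 negative of 11 (11 and 0 adjusted over the list alone), with IL1B at 1.57 and BIRC3 at 1.19. Their median was 1.18 (camera adjusted p = 1.4e-11). Across the androgen-activated targets, 3 differences were positive and 16 negative of 34 (5 and 18 adjusted over the list alone), with PMEPA1 at 1.105. Their median was -0.40 (camera adjusted p = 2.3e-09). Of cell cycle genes, 0 differences were positive and 0 negative of 32 (0 and 0 adjusted over the list alone). Their median was -0.094 (camera adjusted p = 0.20). limma's test passed for 1125 of 16042 genes, 590 higher and 535 lower. The count was 665 and 670 without LNCaP alone DMSO libraries 1 and 2, 616 and 673 without LNCaP alone enzalutamide libraries 1 and 2, and 634 and 580 without CRPCCAF enzalutamide libraries 1 and 2. Of the 22 named genes, 9 lost their call without 1 library.

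For the fibroblasts, the first question was the effect of enzalutamide without TGF-beta1. Serpinb2, an inhibitor of plasminogen activators, averaged 73.6 ± 1.304 TPM against 10.8 ± 0.839 (6.80-fold higher, log2 2.66, SE 0.0464, adjusted p = 2.4e-09). Adamts1 (3.48-fold, log2 -1.79, SE 0.0570), a matrix protease, Fos (4.19-fold, log2 -1.86, SE 0.0785), an immediate early transcription factor, and Rspo2 (3.47-fold, log2 -1.61, SE 0.140), which strengthens Wnt signalling, fell. Spp1, osteopontin, averaged 569.9 ± 9.65 TPM against 959 ± 4.75 (1.68-fold lower, log2 -0.75, SE 0.0152, adjusted p = 5.3e-09). Fkbp5 (1.28-fold, log2 -0.33, SE 0.0714) and Acta2 (1.099-fold, log2 -0.14, SE 0.0122), smooth muscle actin, fell, while Sox4 at 82.8 ± 0.596 TPM against 87.8 ± 0.130 (1.06-fold lower, log2 -0.084, SE 0.0313, adjusted p = 0.083) and Trp53 at 140.3 ± 4.81 TPM against 134 ± 0.526 (1.047-fold higher, log2 0.065, SE 0.106, adjusted p = 0.71) did not pass. Among cholesterol and lipid synthesis genes, 0 rose and 21 fell of 21 (0 and 21 adjusted over the list alone), with Scd2 at -0.79 and Hmgcs1 at -0.72. Their median was -0.67 (camera adjusted p = 2.0e-21). Within cell cycle genes, 1 rose and 24 fell of 32 (1 and 26 adjusted over the list alone), with Cdc20 at -1.34. Their median was -0.70 (camera adjusted p = 2.7e-13). For interferon response genes, 0 rose and 16 fell of 25 (0 and 16 adjusted over the list alone), with Ifit1 at -1.47. Their median was -0.40 (camera adjusted p = 1.8e-06). Across integrated stress and unfolded protein genes, 15 rose and 0 fell of 20 (15 and 0 adjusted over the list alone), with Asns at 0.71. Their median was 0.37 (camera adjusted p = 3.8e-12). Of hypoxia and glycolysis genes, 3 rose and 12 fell of 18 (3 and 12 adjusted over the list alone). Their median was -0.33 (camera adjusted p = 3.0e-05). Among inflammatory CAF genes, 2 rose and 11 fell of 19 (2 and 11 adjusted over the list alone), with Ccl7 at -0.88. Their median was -0.31 (camera adjusted p = 0.00026). Within collagens and matrix genes, 5 rose and 20 fell of 31 (5 and 20 adjusted over the list alone), with Col3a1 at -0.94. Their median was -0.19 (camera adjusted p = 2.6e-05, adjusted p = 0.30 with an estimated correlation). p53 targets, myofibroblastic CAF genes, antigen presentation genes, matrix proteases and inhibitors, and NF-kB and chemokine genes did not pass as lists (camera adjusted p = 0.24, 0.68, 0.97, 0.97 and 0.97), with 1 and 6 of 19, 4 and 8 of 20, 1 and 1 of 11, 7 and 8 of 18, and 5 and 4 of 21 genes higher and lower. For androgen and steroid responsive genes, 6 rose and 6 fell of 15 (7 and 6 adjusted over the list alone), with Mt1 at 1.23. Their median was -0.097, their mean 0.0082 and the test direction up (camera adjusted p = 0.68). Across Sox4 and SWI/SNF subunits, 1 rose and 8 fell of 21 (1 and 10 adjusted over the list alone). Their median was -0.076 (camera adjusted p = 0.022, adjusted p = 0.24 with an estimated correlation). limma's test passed for 3899 of 14988 genes, 1527 higher and 2372 lower, and 3 of 24 named genes, all short RNA genes, lost their call without 1 library.

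TGF-beta response genes need a word on the DMSO columns. A set of 54 TGF-beta signalling genes, written down after the data were examined, lies on steps of 0.3 read in both DMSO columns for 52 of the 53 genes whose steps were solved, and 53 of them lie off whole reads in at least 1 of these columns. Of 17466 other genes, 59 lie off whole reads there, 54 of them on steps of 1 read in 2. Dividing the set by 0.3 brings the DMSO column totals from 986375 and 986203 TPM to within 3.8e-06 and 2.8e-06 of 1e+06, the total of the enzalutamide, TGF-beta1 and ADT columns. The comparisons use the values as deposited, and the values after this division are given beside them, as an alternative chosen after seeing the data. Tgfb1, the ligand itself, averaged 78.7 ± 5.12 TPM against 15.8 ± 1.14 (4.99-fold higher, log2 2.25, SE 0.0562, adjusted p = 1.6e-08) as deposited. With the division its log2 change went from 2.25 to 0.57, Slc20a1 from 2.20 to 0.54, Ppp1r15a from 2.18 to 0.51 and the pathway inhibitor Smad7 from 2.13 to 0.46, all past the test both ways. Of TGF-beta response genes as deposited, 17 rose and 3 fell of 24 (17 and 5 adjusted over the list alone). Their median was 1.62 (camera adjusted p = 5.4e-15). After the division, 12 rose and 3 fell with a median of 0.16 (camera adjusted p = 0.00033). The median ratio of enzalutamide to DMSO over the set was 3.32 as deposited and 0.996 after the division. Of the 53 measured set genes, 51 rose and 0 fell as deposited, and 15 rose and 14 fell after it. The list members outside the set, 10 genes, had a median log2 change of -0.11.

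**Figure D2:**
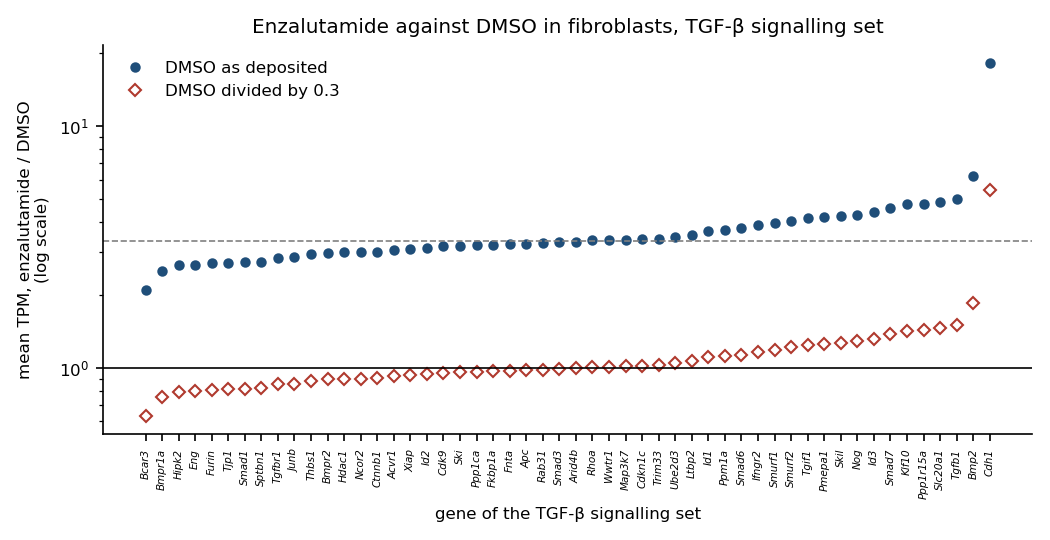
Ratio of the mean TPM under enzalutamide to the mean under DMSO for genes of the TGF-beta signalling set, on a log axis, in CAFs. Blue points use the deposited values and hollow red points the DMSO values divided by 0.3, the solid line marks a ratio of 1 and the dashed line 1 divided by 0.3. Over the whole set the median is 3.32 for the blue points and 0.996 for the red points.

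Among epithelial markers, 1 rose and 1 fell of 12 (0 and 0 adjusted over the list alone). Their median was 0.092 (camera adjusted p = 0.68). Within macrophage and leukocyte markers, 1 rose and 1 fell of 13 (1 and 1 adjusted over the list alone). Their median was -0.25 (camera adjusted p = 0.68). For endothelial markers, 1 rose and 2 fell of 5 (1 and 2 adjusted over the list alone). Their median was -0.37 (camera adjusted p = 0.75). Across pericyte, muscle, fat and glial markers, 1 rose and 6 fell of 8 (1 and 6 adjusted over the list alone). Their median was -0.53 (camera adjusted p = 0.078). In DMSO, 2 of 12 measured epithelial, 13 of 13 macrophage and leukocyte, 5 of 5 endothelial and 8 of 8 pericyte, muscle, fat and glial markers stood at 1 TPM or more. Eng, an endothelial marker, belongs to the set, and after the division the endothelial list had 0 rises and 3 falls (camera adjusted p = 0.015, direction down, adjusted p = 0.078 with an estimated correlation).

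TGF-beta1 alone raised Il11, a fibrosis-linked cytokine, to 689.7 ± 6.74 TPM against 7.32 ± 0.495 (94.2-fold higher, log2 6.38, SE 0.0788, adjusted p = 8.1e-11). Npy (48.5-fold, log2 5.09, SE 0.344), neuropeptide Y, Aldh1a3 (17.2-fold, log2 4.03, SE 0.0362), which makes retinoic acid, Mmp9 (22.5-fold, log2 3.86, SE 0.0677), gelatinase B, and Hbegf (14.1-fold, log2 3.79, SE 0.0263), a ligand of the EGF receptor, rose. Adamts5, an aggrecanase, averaged 21.8 ± 0.464 TPM against 295 ± 5.36 (13.6-fold lower, log2 -3.70, SE 0.0739, adjusted p = 1.5e-09), and Dio3 (18.6-fold, log2 -3.9996, SE 0.0886), which inactivates thyroid hormone, Gas1 (14.9-fold, log2 -3.75, SE 0.0894) and Dhrs3 (13.2-fold, log2 -3.38, SE 0.0860) fell. Fkbp5 averaged 66.0 ± 2.003 TPM against 21.0 ± 2.85 (3.15-fold higher, log2 1.61, SE 0.0714, adjusted p = 1.8e-07). Spp1 (1.90-fold, log2 -0.92, SE 0.0152) and Acta2 (1.35-fold, log2 -0.43, SE 0.0122) fell, while Trp53 at 144 ± 2.69 TPM against 134 ± 0.526 (1.08-fold higher, log2 0.11, SE 0.106, adjusted p = 0.43) did not pass. Sox4 at 86.2 ± 1.77 TPM against 87.8 ± 0.130 (1.02-fold lower, log2 -0.026, SE 0.0313, adjusted p = 0.52) did not pass either, and after median-of-ratios scaling it was higher by 0.077 (adjusted p = 0.044). Of TGF-beta response genes as deposited, 20 rose and 1 fell of 24 (20 and 1 adjusted over the list alone). Their median was 1.67 (camera adjusted p = 1.6e-16). After the division, 15 rose and 4 fell with a median of 0.62 (camera adjusted p = 1.8e-07). Tgfb1 went from 4.11 to 2.44 with it. Over the set, 52 of 53 genes rose as deposited, and 25 rose and 17 fell after it. Among interferon response genes, 0 rose and 23 fell of 25 (0 and 23 adjusted over the list alone), with Ifit1 at -3.02 and Ifit3 at -3.03. Their median was -1.16 (camera adjusted p = 6.7e-08). Within cell cycle genes, 1 rose and 29 fell of 32 (1 and 30 adjusted over the list alone). Their median was -0.98 (camera adjusted p = 2.3e-09). For myofibroblastic CAF genes, 5 rose and 15 fell of 20 (5 and 15 adjusted over the list alone), with Tnc at 1.82. Their median was -0.33 (camera adjusted p = 0.021, adjusted p = 0.084 with an estimated correlation). Across pericyte, muscle, fat and glial markers, 1 rose and 6 fell of 8 (1 and 6 adjusted over the list alone). Their median was -1.04 (camera adjusted p = 0.12). Of endothelial markers, 1 rose and 4 fell of 5 (1 and 4 adjusted over the list alone). Their median was -0.38 (camera adjusted p = 0.88). limma's test passed for 8030 of 14988 genes, 2847 higher and 5183 lower, and after median-of-ratios scaling the split was 3903 higher and 3896 lower.

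With enzalutamide and TGF-beta1 together, Trp53, the gene of p53, averaged 6.16 ± 0.693 TPM against 134 ± 0.526 (21.8-fold lower, log2 -4.24, SE 0.106, adjusted p = 1.4e-09). Nos2, inducible nitric oxide synthase, averaged 54.1 ± 0.338 TPM against 0.0913 ± 0.0725 (592-fold higher, log2 5.66, SE 0.0692, adjusted p = 2.1e-11), and Mmp9 374 ± 0.109 TPM against 1.69 ± 0.221 (221-fold higher, log2 7.13, SE 0.0677, adjusted p = 5.4e-12). Eno1b (432-fold, log2 8.27, SE 0.131), a copy of the enolase gene, and Fgf21 (135-fold, log2 4.85, SE 0.0943), a metabolic hormone, rose. Igfbp2, a binder of insulin-like growth factors, averaged 0.192 ± 0.0164 TPM against 367 ± 6.97 (1907-fold lower, log2 -8.27, SE 0.0825, adjusted p = 6.6e-12). Gas6 (326-fold, log2 -7.76, SE 0.122), a ligand of the AXL receptor, Cemip (172-fold, log2 -7.14, SE 0.0409), which degrades hyaluronan, and Mgp (144-fold, log2 -6.91, SE 0.195), matrix Gla protein, fell. Sox4 averaged 160.3 ± 3.10 TPM against 87.8 ± 0.130 (1.83-fold higher, log2 0.86, SE 0.0313, adjusted p = 1.5e-08) and Spp1 3619 ± 43.8 TPM against 959 ± 4.75 (3.77-fold higher, log2 1.91, SE 0.0152, adjusted p = 2.6e-12). Fkbp5 (3.43-fold, log2 1.74, SE 0.0714) rose and Acta2 (3.003-fold, log2 -1.59, SE 0.0122) fell. Among cell cycle genes, 32 rose and 0 fell of 32 (32 and 0 adjusted over the list alone), with Mcm5 at 1.73 and Top2a at 1.81. Their median was 1.60 (camera adjusted p = 8.0e-15). Within p53 targets, 1 rose and 17 fell of 19 (1 and 17 adjusted over the list alone), with Ccng1 at -4.003 and Cdkn1a at -2.85. Their median was -1.84 (camera adjusted p = 7.2e-06). For interferon response genes, 19 rose and 4 fell of 25 (19 and 4 adjusted over the list alone), with Isg15 at 2.95. Their median was 0.77 (camera adjusted p = 0.00084). Across TGF-beta response genes as deposited, 13 rose and 11 fell of 24 (13 and 11 adjusted over the list alone). Their median was 0.25 (camera adjusted p = 0.19). After the division, 8 rose and 16 fell with a median of -0.63 (camera adjusted p = 0.10). Of macrophage and leukocyte markers, 0 rose and 11 fell of 13 (0 and 11 adjusted over the list alone), with Lyz2 at -4.49. Their median was -1.03 (camera adjusted p = 0.057). Among epithelial markers, 2 rose and 1 fell of 12 (2 and 1 adjusted over the list alone). Their median was 0.055 (camera adjusted p = 0.52). Within pericyte, muscle, fat and glial markers, 1 rose and 6 fell of 8 (1 and 6 adjusted over the list alone). Their median was -2.06 (camera adjusted p = 0.13). For endothelial markers, 1 rose and 3 fell of 5 (1 and 3 adjusted over the list alone). Their median was -1.055 (camera adjusted p = 0.51). limma's test passed for 11079 of 14988 genes, 4701 higher and 6378 lower as deposited and 5627 higher and 5343 lower after median-of-ratios scaling. The median log2 change of all genes was -0.12, and 0.0025 after median-of-ratios scaling. A cell stock shared with the ADT mice or a wrong label is not excluded for these libraries, so the values need not be effects of the agents.

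**Figure D3:**
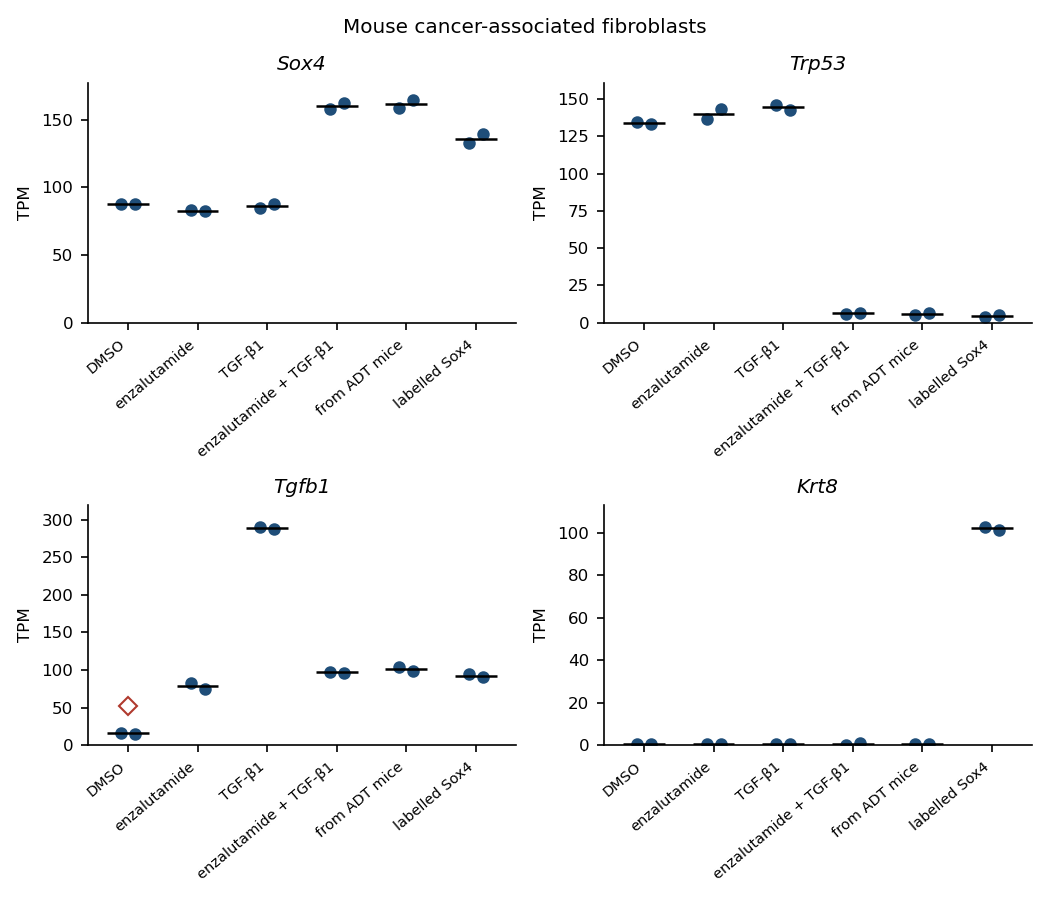
TPM of Sox4, Trp53, Tgfb1 and Krt8 in each library of the 6 CAF groups, on the y axis of each panel, with points for the 2 libraries of a group and a black bar for their mean. The hollow red diamond is the DMSO mean of Tgfb1 divided by 0.3. Trp53 is low in the groups with both agents, from ADT mice and labelled Sox4, and Krt8 is high in the Sox4-labelled group.

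Enzalutamide against DMSO was next compared between libraries labelled with and without TGF-beta1, as a difference of effects, with minus without. Eno1b differed by 8.12 (SE 0.185, adjusted p = 1.5e-09), the neutrophil chemokine Cxcl5 by 6.27 (SE 0.0722, adjusted p = 3.6e-11), the interferon-induced genes Cxcl10 by 5.89 (SE 0.261, adjusted p = 1.0e-07) and Isg15 by 5.50 (SE 0.165, adjusted p = 8.0e-09), and Il11 by -8.22 (SE 0.111, adjusted p = 7.5e-11). Igfbp2 differed by -8.13 (SE 0.117, adjusted p = 9.9e-11) and Npy by -6.01 (SE 0.486, adjusted p = 5.6e-06). Trp53 differed by -4.41 (SE 0.150, adjusted p = 1.8e-08), Sox4 by 0.97 (SE 0.0442, adjusted p = 1.2e-07), Spp1 by 3.59 (SE 0.0214, adjusted p = 9.9e-13), Acta2 by -1.02 (SE 0.0172, adjusted p = 2.7e-10) and Fkbp5 by 0.46 (SE 0.101, adjusted p = 0.0036). Across interferon response genes, 25 differences were positive and 0 negative of 25 (25 and 0 adjusted over the list alone). Their median was 2.16 (camera adjusted p = 5.2e-11). Of cell cycle genes, 32 differences were positive and 0 negative of 32 (32 and 0 adjusted over the list alone). Their median was 3.28 (camera adjusted p = 1.4e-18). Among p53 targets, 3 differences were positive and 15 negative of 19 (3 and 15 adjusted over the list alone). Their median was -1.33 (camera adjusted p = 1.1e-05). Within TGF-beta response genes as deposited, 3 differences were positive and 21 negative of 24 (3 and 21 adjusted over the list alone). Their median was -2.76 (camera adjusted p = 4.8e-10). After the division, 3 were positive and 21 negative with a median of -1.52 (camera adjusted p = 3.3e-08). limma's test passed for 9538 of 14988 genes, 4605 higher and 4933 lower as deposited and 4837 higher and 4652 lower after median-of-ratios scaling. As the libraries with both agents enter each value here, none need be a difference of drug effects.

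CAFs from ADT mice were next set against CAFs in DMSO. The first were collected at day 0 and the second at day 7, so origin, day and vehicle go together. Trp53 averaged 5.91 ± 0.841 TPM against 134 ± 0.526 (22.7-fold lower, log2 -4.29, SE 0.106, adjusted p = 1.3e-09). Sox4 averaged 162 ± 4.43 TPM against 87.8 ± 0.130 (1.84-fold higher, log2 0.87, SE 0.0313, adjusted p = 1.3e-08) and Spp1 3431 ± 14.8 TPM against 959 ± 4.75 (3.58-fold higher, log2 1.84, SE 0.0152, adjusted p = 3.0e-12). Mmp9 (242-fold, log2 7.26, SE 0.0677), Nos2 (558-fold, log2 5.58, SE 0.0692) and Eno1b (431-fold, log2 8.27, SE 0.131) were higher and Igfbp2 (2448-fold, log2 -8.32, SE 0.0825), Gas6 (260.5-fold, log2 -7.53, SE 0.122) and Sfrp1 (87.6-fold, log2 -5.94, SE 0.0550), a Wnt antagonist, lower. Fkbp5 (3.57-fold, log2 1.79, SE 0.0714) was higher and Acta2 (2.99-fold, log2 -1.58, SE 0.0122) was lower. For cell cycle genes, 32 rose and 0 fell of 32 (32 and 0 adjusted over the list alone). Their median was 1.66 (camera adjusted p = 7.0e-15). Across p53 targets, 2 rose and 17 fell of 19 (2 and 17 adjusted over the list alone). Their median was -1.75 (camera adjusted p = 1.2e-05). Of TGF-beta response genes as deposited, 13 rose and 10 fell of 24 (13 and 10 adjusted over the list alone). Their median was 0.22 (camera adjusted p = 0.17). After the division, 8 rose and 16 fell with a median of -0.65 (camera adjusted p = 0.11). Among macrophage and leukocyte markers, 1 rose and 11 fell of 13 (1 and 11 adjusted over the list alone), with Lyz2 at -4.02. Their median was -1.104 (camera adjusted p = 0.076). Within epithelial markers, 2 rose and 1 fell of 12 (2 and 1 adjusted over the list alone). Their median was 0.066 (camera adjusted p = 0.65). For pericyte, muscle, fat and glial markers, 1 rose and 6 fell of 8 (1 and 6 adjusted over the list alone). Their median was -2.002 (camera adjusted p = 0.12). Across endothelial markers, 1 rose and 3 fell of 5 (1 and 3 adjusted over the list alone). Their median was -1.1002 (camera adjusted p = 0.64). limma's test passed for 11172 of 14988 genes, 4719 higher and 6453 lower as deposited and 5704 higher and 5336 lower after median-of-ratios scaling. The median log2 change of all genes was -0.13, and 0.0086 after median-of-ratios scaling.

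A comparison chosen after seeing the data set the libraries with both agents against those from ADT mice. limma's test passed for 5 of 14988 genes, 4 higher and 1 lower, where 1297 had an unadjusted p under 0.05. They include Htr2a (log2 change 0.28, SE 0.0311, adjusted p = 0.037), Mir7041 (log2 change 1.87, SE 0.131, adjusted p = 0.0041), Mir7050 (log2 change 1.72, SE 0.158, adjusted p = 0.019) and LOC115485679 (log2 change 1.85, SE 0.192, adjusted p = 0.025), the last of which is outside the rule for named genes and was chosen after its values were seen. Htr2a, a serotonin receptor, averaged 27.5 ± 0.0784 TPM against 22.5 ± 0.179, and Mir7041, Mir7050 and LOC115485679 were listed at 0 in the ADT libraries. Trp53 averaged 6.16 ± 0.693 TPM against 5.91 ± 0.841 (1.04-fold higher, log2 0.053, SE 0.106, adjusted p = 0.96) and Sox4 160.3 ± 3.10 TPM against 162 ± 4.43 (1.01-fold lower, log2 -0.012, SE 0.0313, adjusted p = 0.97), and neither passed, nor did Spp1, Acta2 or Fkbp5. Of cell cycle genes, 0 rose and 0 fell of 32 (0 and 0 adjusted over the list alone). Their median was -0.014 (camera adjusted p = 0.55). All 4 named genes past the test lost their call without 1 library. The count was 0 without ADT library 1, 0 without ADT library 2 and 11 without library 2 of both agents, and at an unadjusted p under 0.05 the counts of 0 became 762 and 1018 genes. Without the Sox4-labelled columns it was 2.

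The columns labelled as Sox4-overexpressing CAFs differ in make from the rest. Of their solved values, 11.4% and 11.5% lie on whole reads, which decides nothing without a read number of their own. They total 923739 and 923712 TPM. 1301 and 1341 genes above 0 equal the same-numbered ADT column to within 1e-06 of the value. Deposited values are compared below. limma takes columns as independent that by these equal values are not. Its p values for them do not test a difference between cells. Every CAF SE and p value shares their residuals, which nearly repeat ADT's. Against DMSO, the simple-epithelium keratin Krt8 averaged 102 ± 0.773 TPM against 0.450 ± 0.0370 (226-fold higher, log2 6.15, SE 0.169, adjusted p = 2.4e-09), and Krt18 (477-fold, log2 6.19, SE 0.248) and Krt7 (216-fold, log2 6.23, SE 0.154) were higher too. The epithelial genes Wfdc2 at 66.7 ± 2.18 TPM against listed at 0 and Cldn4 at 58.4 ± 0.166 TPM against listed at 0 were also higher. Sox4 averaged 136 ± 4.48 TPM against 87.8 ± 0.130 (1.55-fold higher, log2 0.63, SE 0.0313, adjusted p = 1.2e-07), Trp53 4.62 ± 0.735 TPM against 134 ± 0.526 (29.0-fold lower, log2 -4.59, SE 0.106, adjusted p = 7.9e-10) and Spp1 3207 ± 15.0 TPM against 959 ± 4.75 (3.34-fold higher, log2 1.74, SE 0.0152, adjusted p = 3.2e-12). Mmp9 (232-fold, log2 7.19, SE 0.0677), Nos2 (434-fold, log2 5.22, SE 0.0692) and Fkbp5 (3.09-fold, log2 1.59, SE 0.0714) were higher and Gas6 (1812-fold, log2 -8.90, SE 0.122), Igfbp2 (595-fold, log2 -7.84, SE 0.0825) and Acta2 (3.04-fold, log2 -1.60, SE 0.0122) lower. Among epithelial markers, 10 rose and 1 fell of 12 (10 and 1 adjusted over the list alone), with Krt14 at 3.71 and Cdh1 at 3.67. Their median was 3.43 (camera adjusted p = 7.4e-06). Within macrophage and leukocyte markers, 0 rose and 11 fell of 13 (1 and 11 adjusted over the list alone). Their median was -1.197 (camera adjusted p = 0.080). For pericyte, muscle, fat and glial markers, 1 rose and 6 fell of 8 (1 and 6 adjusted over the list alone). Their median was -2.05 (camera adjusted p = 0.23). Across cell cycle genes, 32 rose and 0 fell of 32 (32 and 0 adjusted over the list alone). Their median was 1.53 (camera adjusted p = 3.2e-17). Of p53 targets, 2 rose and 17 fell of 19 (2 and 17 adjusted over the list alone). Their median was -1.82 (camera adjusted p = 4.5e-05). Among TGF-beta response genes as deposited, 10 rose and 11 fell of 24 (10 and 11 adjusted over the list alone). Their median was -0.064, their mean -0.027 and the test direction up (camera adjusted p = 0.27). After the division, 5 rose and 16 fell with a median of -0.76 (camera adjusted p = 0.059). limma's test passed for 11350 of 14988 genes, 3962 higher and 7388 lower, and after median-of-ratios scaling the split was 5806 higher and 5349 lower. The median log2 change of all genes was -0.25, and 0.025 after that scaling.

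CAFs from ADT mice were set against the Sox4-labelled columns, both at day 0. Of 6322 and 6361 genes at 20 TPM or more in ADT columns 1 and 2, 0 and 0 lay higher in the same-numbered Sox4-labelled column, so for such genes the make of the columns sets the direction. Krt8 averaged 0.400 ± 0.00934 TPM against 102 ± 0.773 (255-fold lower, log2 -6.20, SE 0.169, adjusted p = 2.0e-07), and Krt7 (836-fold, log2 -6.65, SE 0.154), Lcn2 (155-fold, log2 -6.18, SE 0.228), Clu (62.3-fold, log2 -5.45, SE 0.164), clusterin, and Epcam (75.9-fold, log2 -4.76, SE 0.236), an epithelial adhesion protein, were lower. Lif, a cytokine of the IL-6 family, averaged 30.4 ± 0.477 TPM against 1.85 ± 1.78 (16.4-fold higher, log2 3.62, SE 0.339, adjusted p = 0.00022), and Col7a1 (9.86-fold, log2 2.78, SE 0.180), Col18a1 (5.52-fold, log2 2.25, SE 0.164) and Cxcl16 (7.11-fold, log2 2.51, SE 0.204) were higher. Sox4 stood at 162 ± 4.43 TPM against 136 ± 4.48 (1.19-fold higher, log2 0.25, SE 0.0313, adjusted p = 0.0012), and at 0.096 after median-of-ratios scaling it did not pass (adjusted p = 0.14). Spp1 changed by 0.098 (adjusted p = 0.0033), and by -0.055 after that scaling (adjusted p = 0.16). Acta2 stood at 0.022 (adjusted p = 0.25) and at -0.13 (adjusted p = 0.0021) after it. Fkbp5 and Trp53 did not pass. Within epithelial markers, 1 rose and 10 fell of 12 (1 and 10 adjusted over the list alone). Their median was -3.62 (camera adjusted p = 2.4e-49). limma's test passed for 2940 of 14988 genes, 2805 higher and 135 lower, and after median-of-ratios scaling for 547, 290 higher and 257 lower, as the median log2 change of all genes went from 0.11 to -0.021. The count was 1312 and 1862 without Sox4-labelled columns 1 and 2, and 1419 and 1117 without ADT libraries 1 and 2.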

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

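All tests of explanations in this part were chosen after the results were seen, as was the comparison of both agents with the ADT mice, while the tests of differences between effects were fixed before. Those tests compare the effect of enzalutamide, as the libraries are labelled, between 2 kinds of culture.

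With CCAFs minus alone, 1125 genes differed in limma's test. The count was 642 without LNCaP alone DMSO library 1, 623 without LNCaP alone enzalutamide library 1, 648 and 628 without CCAF DMSO libraries 1 and 2, and 718 and 647 without CCAF enzalutamide libraries 1 and 2. Positive log2 differences were MIR4489 at 3.17, RN7SKP203 at 2.47, CP at 2.40, KLK3 at 2.28, SNORD4B at 2.16, MIR658 at 2.01, TMEM238 at 1.81, RRM2 at 1.76, SNORD142 at 1.75 and MIR659 at 1.69. Negative differences were MIR296 at -2.03, HMOX1 at -1.78, AKAP12 at -1.74, SNORA86 at -1.71, IGFBP3 at -1.66, MIR200B at -1.55, MIR6804 at -1.44, ANGPT2 at -1.37, SMAD9 at -1.25 and RMRP at -1.23. The calls of MIR4489, RN7SKP203, SNORD4B, MIR658, TMEM238, SNORD142, MIR659, MIR200B and MIR6804 ended when 1 library was left out, as did that of 1 gene not reported here, and most of these are short RNA genes.

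With CRPCCAFs minus alone, 1125 genes differed as well. The count was 665 and 670 without LNCaP alone DMSO libraries 1 and 2, 616 and 673 without LNCaP alone enzalutamide libraries 1 and 2, and 634 and 580 without CRPCCAF enzalutamide libraries 1 and 2. Positive log2 differences were CP at 3.48, MIR1249 at 3.10, MIR103A2 at 2.72, IGFBP5 at 2.60, SDCBP2 at 2.40, FKBP1A-SDCBP2 at 2.30, LCN2 at 2.08, SNORA16B at 2.07, MAN1A1 at 2.06, NFKBIZ at 1.96 and KLK3 at 0.86. Negative differences were TRNAG27 at -2.53, VSTM2L at -2.27, MIR1324 at -2.05, IGFBP3 at -1.89, MIR6804 at -1.87, PHGR1 at -1.79, TRNAC-GCA at -1.78, SNORA24 at -1.68, MMP7 at -1.58, HIST1H4H at -1.4996 and FKBP5 at -0.65. The calls of MIR1249, MIR103A2, SNORA16B, TRNAG27, MIR1324, MIR6804, PHGR1, TRNAC-GCA and SNORA24 ended when 1 library was left out.

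In CAFs with TGF-beta1 minus without, 9538 genes differed. Positive log2 differences were Eno1b at 8.12, Cxcl5 at 6.27, Cxcl10 at 5.89, Nos2 at 5.67, Capn6 at 5.57, Isg15 at 5.50, Steap4 at 5.26, Oasl2 at 5.20, Cxcl1 at 5.17, Oasl1 at 5.10, Sox4 at 0.97, Spp1 at 3.59 and Fkbp5 at 0.46. Negative differences were Il11 at -8.22, Igfbp2 at -8.13, Gas6 at -6.20, Npy at -6.01, Lce1g at -5.83, Cemip at -5.82, Tnfsf15 at -5.78, Mir377 at -5.63, Acta1 at -5.61, Mustn1 at -5.57, Acta2 at -1.02 and Trp53 at -4.41.

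The first pattern weighed is the low level of 54 TGF-beta signalling genes in both DMSO columns of the CAFs. Of the 53 set genes with solved steps, 53 lay off whole reads in at least 1 DMSO column, which argues against lower expression in DMSO as the whole cause, since reads of an expressed gene come whole. 52 lay on steps of 0.3 read in both columns, as a multiplication of the deposited values by 0.3 would give, and this may be how they arose. Where and why such a step entered, and whether it was meant, stays open. The division brought both DMSO totals to 1e+06, arguing against the deposited rise being all response. Log2 medians went from 1.65 to -0.0062 for the set and 1.96 to 0.26 for its 14 response genes.

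The second pattern is that the Sox4-labelled columns follow the same-numbered ADT columns gene by gene. Shares of at most 11.5% on whole reads decide nothing without a read number. At least 1301 genes equalled the ADT value, against separate libraries and mixed-in epithelial cells, as added reads rescale every gene. In the lower of the 2 columns, 99.8% of the differing values lay on whole steps of 1 further profile around the ADT value, and 17.3% around the other ADT column, so the columns may be the absolute difference of the ADT column and about 8% of a further profile. The share rests on a rule for signs that was set after the total was seen. Scaled to TPM, that profile holds epithelial Krt8 (1279) and Epcam (507) but also Spp1 (2807), Col1a1 (524) and Sox4 (321). Its origin was not tested.

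The third pattern is that the libraries with enzalutamide and TGF-beta1 resemble those from ADT mice, with 5 genes past limma's test between them. The chi-square per gene between a library of each ran from 1.85 to 2.65 (within CAF groups 1.39 to 1.69), where 1 library read again would give about 1 and a bound of 1.5 was set, which argues against the same libraries under 2 labels. Of 679 genes changed over 2-fold with both agents and by under 0.25 log2 with each alone, 91.3% lay within 0.25 log2 of the ADT mean, but so did 90.3% of the other tested genes, so this decides nothing, and the 5 genes are the pattern itself and do not test a response of the same fibroblasts to both agents. Trp53 averaged 6.16 TPM with both agents and 5.91 from ADT mice against 134 in DMSO and 140.3 and 144 with each agent alone. That response cannot be told apart from a shared cell stock or a wrong label, because the treatment was given in this group only and day differs too.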

How the results depend on the processing

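The alternatives fixed beforehand are the pseudocount, the filter, the scaling, the block and the libraries left out. All other alternatives and the comparison of both agents with the ADT mice were chosen after seeing the data. Counts of genes stayed within 1.5 times under a pseudocount of 0.1, the block, the division by 0.3 and without the libraries with both agents. With each library left out in turn, 30 of 88 counts moved by more. The ranges were 640 to 824 for CCAFs against alone under DMSO, 821 to 1962 for CRPCCAFs against CCAFs under DMSO, 1672 to 1951 for CCAFs against alone under enzalutamide, 623 to 813 and 580 to 1121 for the differences of the enzalutamide effect with CCAFs and CRPCCAFs, 1117 to 1862 for ADT against the Sox4-labelled columns, and 0 to 11 for both agents against ADT. A fit with fewer libraries has a lower power, and no other cause was tested. Median-of-ratios scaling moved ADT against the Sox4-labelled columns to 547, of which 448 genes were also called as deposited. For both agents against ADT, the count was 39 with no filter and 2 without the Sox4-labelled columns, whose residuals the main fit uses. The cause was not tested.

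Of 449 named results, 420 passed as deposited and 355 under all alternatives run and with each library left out. The other changes were 211 lost calls with a library left out, 40 without a filter, 22 with a pseudocount of 0.1, 9 with the block, 2 without the Sox4-labelled columns and 1 with the scaling. 3 calls were gained with a library left out and 2 with the block. The direction reversed for MMP7 in the difference with CRPCCAFs, to 0.74 with a pseudocount of 0.1, and under median-of-ratios scaling for Sox4 with TGF-beta1, to 0.077, and for Spp1 and Acta2 in ADT against the Sox4-labelled columns, to -0.055 and -0.13. The cause was not tested. Of 328 list tests, 60 were lost with an estimated correlation. The planned tests on read counts were not run, because the tables hold RPKM and TPM, although reads could be recovered for most genes. Recovery of changes in simulated data need not hold here, and what depth adds was not tested.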

Other observations

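The values in this part were chosen after seeing the data. No list of retinoid genes was fixed. CYP26A1 averaged 0.0510 RPKM in LNCaP alone, 11.3 with CRPCCAFs and 32.0 with enzalutamide too (2 libraries each). DHRS3 averaged 4.99, 49.9 and 75.3 RPKM in the same groups and 15.1 with CCAFs (limma against alone: log2 1.43, SE 0.0835, adjusted p = 6.0e-06). ALDH1A3, which makes retinoic acid, fell with enzalutamide alone, from 29.7 to 11.5 RPKM, and rose with CRPCCAFs, from 52.9 to 77.3 RPKM (limma's difference of effects: log2 1.83, SE 0.0615, adjusted p = 1.1e-06). With CRPCCAFs against alone under DMSO, RARA (log2 0.57, SE 0.115, adjusted p = 0.0051) and TGM2 (log2 1.14, SE 0.139, adjusted p = 0.00028) were higher and RARB, CRABP2 and RARRES3 did not pass (limma adjusted p = 0.37, 0.23 and 0.15). Under enzalutamide, RARA (log2 0.71, adjusted p = 0.0011), CRABP2 (log2 0.80, adjusted p = 0.0057) and RARRES3 (log2 0.71, adjusted p = 0.025) were higher and RARB and TGM2 did not pass (adjusted p = 0.83 and 0.25). Enzalutamide beside CRPCCAFs lowered TGM2 (log2 -0.93) and RARB (-0.62, alone -0.80, with CCAFs -0.53). RARA (0.38), CRABP2 (0.57) and RARRES3 (1.38) rose. Of these, only TGM2's fall differed from alone (-0.92, adjusted p = 0.025).

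Enzalutamide's effects were compared across the cultures, which share no libraries, over 16042 genes that are not independent of each other. Between LNCaP alone and with CCAFs, Pearson's r was 0.813, Spearman's rho 0.809 and the slope 0.673. 3545 genes rose and 2921 fell in both, where independent calls give 1297 and 872, and 50 were called in opposite directions. Between LNCaP alone and with CRPCCAFs, r was 0.827, rho 0.795 and the slope 0.832, with 3704 genes higher and 3211 lower in both and 121 in opposite directions. Between the cocultures, r was 0.812, rho 0.795 and the slope 0.985, with 3520 higher, 2866 lower and 64 opposite.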
